A study of Arabidopsis thaliana with 16 samples.

How the data were processed

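Per the submitters' processing notes, RNA came from roots (RNeasy kit), integrity was read on a Bioanalyzer, TruSeq mRNA libraries were sequenced as 100 bp paired ends on a HiSeq 2000, and reads were aligned with BWA 0.7.7 to TAIR10. The deposited files hold, per the file headers, a read count, a length and RPKM for each of 39640 transcript models, and each of the 16 count columns summed to its header total. The authors' RPKM could be recomputed from count, length and total to within 3.6e-11. The median ratio of the file length to the annotated span with introns was 0.964, and 1.415 to the spliced length. RPKM was therefore not used for levels, and the deposited counts were used throughout. The counting tool, the strand setting, the treatment of reads shared by several models and whether mates were counted singly are not given in the sources used here. All 16 totals were even, so both mates may be counted, with 50.1 to 52.5% even among counts of 20 or more.

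Counts of models were summed to 33518 loci, of which 4626 had 2 or more models, and 32709 loci matched the reference table by locus tag. The reference is TAIR10.1, which differs in name from the build of the files, so it served for names and neighbours and no coordinates are printed. Loci were filtered with filterByExpr, which left 22304. Libraries were scaled by TMM and tested in edgeR 4.0.16 with the quasi-likelihood F test on 8 group means, and p-values were adjusted by Benjamini-Hochberg over the loci tested. A locus was called at an adjusted p below 0.05. The groups, 20 contrasts, 20 gene lists of 284 members and most alternatives were set before the data were seen. Genes were named by a rule set at the same time: called, with a mean of at least 5 CPM over the libraries of the contrast and no overlap between the libraries compared (for a difference or average of 2 contrasts, at least in the larger), the 8 largest rises and falls in the 4 main contrasts and 3 in each other, besides members of the lists, with RSL4, RSL2, EXPA7 and EBF2 always. The standard error is the log2 fold change over the square root of F. The common biological coefficient of variation was 0.0938. All adjusted p-values of genes come from edgeR, unless DESeq2 1.42.0 is named, and those of lists come from camera in limma 3.58.1 on log CPM with a prior count of 2. Camera used a preset correlation of 0.01 between genes and was repeated with an estimated correlation. Of 380 list tests 133 were called with the preset, 21 with the estimated correlation and 138 with replicate number as a block. The list of the 4 targeted genes was not tested. Single values of some list members are not reported here. Gene families were grouped by annotation after the data had been seen, and of 120 tests 35 were called, though 0 with an estimated correlation.

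CPM values are scaled by the TMM library sizes. Where a group had no read, folds are given against 3 reads over the group's libraries, and where it had 1 to 3 reads as a ratio of counts with a 95% interval. These cover counting error only, as reads without molecular identifiers, or mates, are not independent. Lists were also given a median with such genes at their bound. Expected overlaps of independent lists are the product of both list sizes over the loci tested. For contrasts with shared controls 10 simulations without effects were run with the measured dispersion. The test of EIN3/EIL1 dependence for loci silent in untreated rhd6rsl1 first read only replicate 2 of the treated quadruple mutant, against a limit of 10%. It was replaced, with the values already seen, by the share of loci called lower with all 4 libraries, and replicate 1, at 14.9%, would not have met the first limit. The admixture and shoot tissue tests of ein3eil1rhd6rsl1_ethylene replicate 1 were likewise set to undecided after their values were seen. In some contrasts a fold was planted in 200 loci. At 1.5-fold 48.2% of changed and tested loci were recovered for ethylene in Col-0, 5.08% for the EIN3/EIL1-dependent response, 45.7% for ein3eil1 against Col-0 under ethylene and 75.3% for rhd6rsl1 against Col-0 balanced. At 2-fold recoveries were 72.6, 61.4, 71.1 and 84.6%, and at 4-fold 90.5, 84.9, 89.9 and 97.4%. The analysis ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.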

Results

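Root RNA was sequenced from Arabidopsis thaliana seedlings of 4 genotypes to ask how ethylene promotes root hair growth through EIN3/EIL1 and RHD6/RSL1. The genotypes were the wild type Col-0, the ein3eil1 double mutant, the rhd6rsl1 double mutant and the quadruple mutant ein3eil1rhd6rsl1. EIN3 and EIL1 are the main transcription factors of ethylene signalling, and RHD6 and RSL1 are bHLH factors that start root hair formation. Seedlings had grown for 6 d on vertical plates and were left untreated or exposed to 10 ppm ethylene for 4 h. The 8 groups had 2 biological replicates each, which gave 16 libraries of 33.0M to 45.0M assigned reads. Replicates correlated at r of 0.984 to 0.992 across loci. The first principal component held 41.4% of the variance and the second 27.4%. Levels are CPM (counts scaled to library size), given as mean ± SD of n = 2, and changes are log2 fold changes ± standard error. All p-values compare biological replicates as the series design describes them.

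The codes of the deposited files carry 1 of 2 letters, S or Z, whose meaning is not given in the sources used here. Set S held untreated rhd6rsl1, untreated quadruple mutant, and Col-0 and ein3eil1 with ethylene, and set Z held the other 4 groups. Any ethylene effect within 1 genotype was therefore also a contrast of S with Z, as was any contrast of rhd6rsl1 with Col-0 at 1 treatment. The contrasts of ein3eil1 with Col-0 and of the quadruple mutant with rhd6rsl1 each lay within 1 set. In differences of the ethylene responses of Col-0 and ein3eil1, or of rhd6rsl1 and the quadruple mutant, an additive set effect cancels. It also cancels in genotype contrasts averaged over both treatments, but doubles where responses of Col-0 and rhd6rsl1, or of ein3eil1 and the quadruple mutant, are subtracted. In 2 libraries transcripts of photosynthesis genes were high. Their summed level was 1110 CPM in Col-0_ethylene replicate 1 against 283 CPM in replicate 2. In ein3eil1rhd6rsl1_ethylene replicate 1 it was 1860 CPM against 368 CPM in replicate 2, and the other libraries held 273 to 535 CPM.

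**Figure D1:**
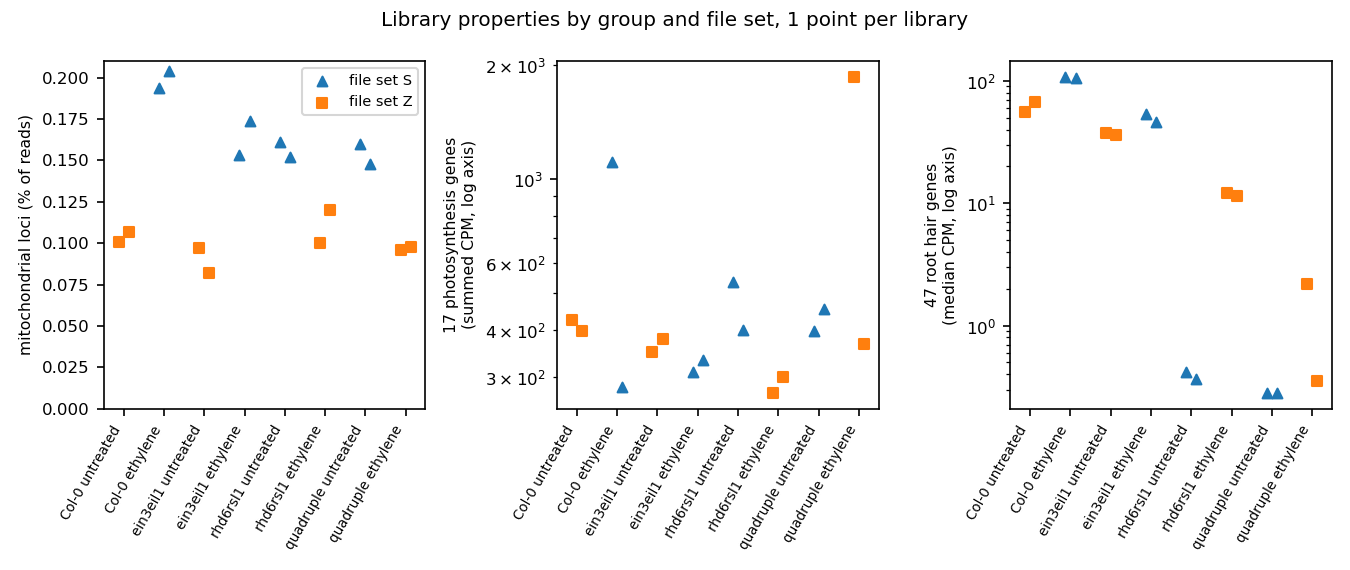
Share of mitochondrial reads, summed CPM of 17 photosynthesis genes and median CPM of 47 root hair genes in each library (points) by group and file set. The mitochondrial share follows the file set, and 1 library each of Col-0 and the quadruple mutant with ethylene is high in photosynthesis transcripts.

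The 4 targeted genes were first read in every library. EIN3 (AT3G20770) stood at 148 to 185 CPM in the 8 libraries of Col-0 and rhd6rsl1 and at 28.7 to 41.6 CPM in the 8 libraries of ein3eil1 and the quadruple mutant. EIL1 (AT2G27050) stood at 61.3 to 75.6 CPM in the former and at 12 to 29.7 CPM in the latter. RHD6 (AT1G66470) was at 23.9 ± 0.47 CPM in untreated Col-0 and 21.3 ± 0.59 CPM in untreated ein3eil1, but at 7.92 ± 0.0071 CPM in untreated rhd6rsl1 and 6.92 ± 0.62 CPM in the untreated quadruple mutant. With ethylene it was at 15 ± 1.1 CPM in Col-0 and 15.2 ± 0.61 CPM in rhd6rsl1. RSL1 (AT5G37800) was at 5.85 ± 0.0092 CPM in untreated Col-0, 1.93 ± 0.098 CPM in untreated rhd6rsl1 and 2.03 ± 0.011 CPM in the untreated quadruple mutant. With ethylene RSL1 was at 1.42 ± 0.46 CPM in Col-0 and 1.49 ± 0.36 CPM in rhd6rsl1, against 5.43 ± 0.28 CPM in ein3eil1. Reads at a mutated locus need not come from a functional transcript, and the alleles are not named in the sources used here.

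**Figure D2:**
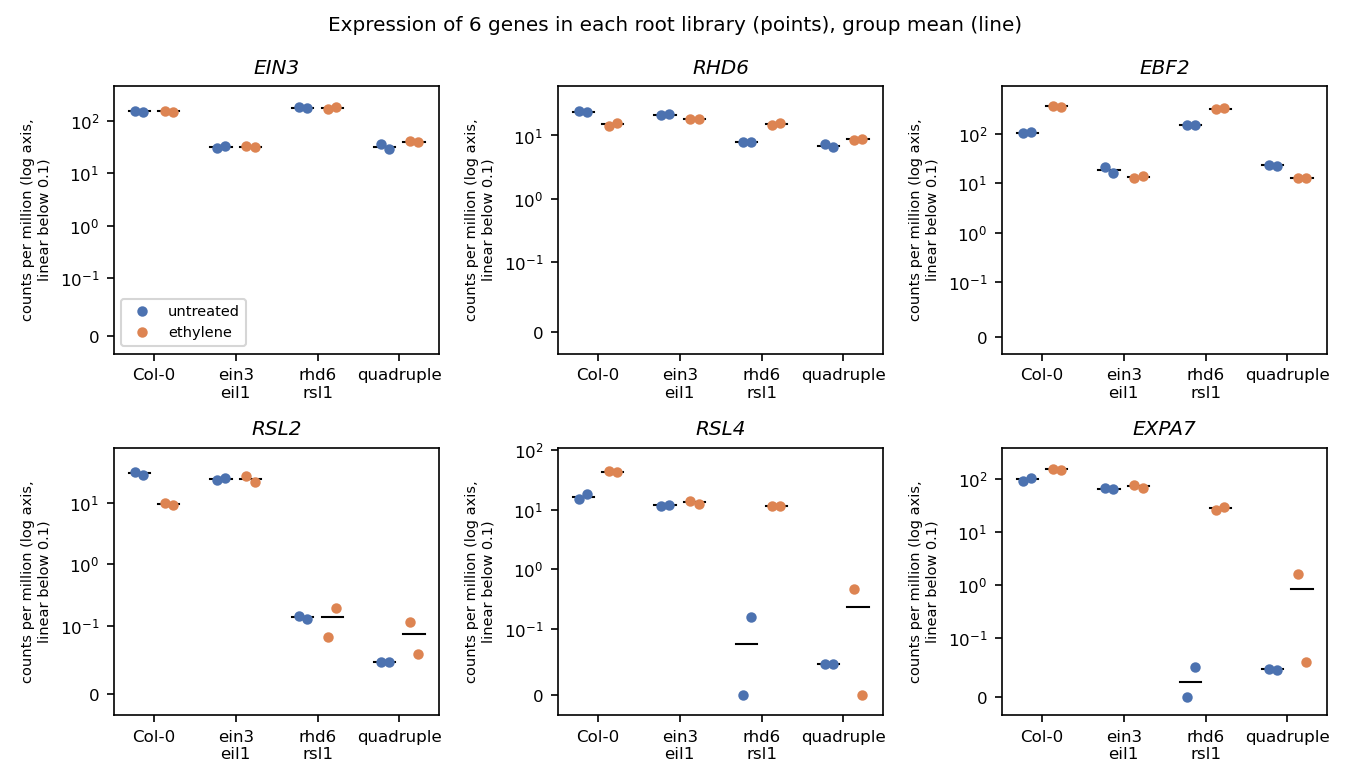
CPM (log axis, linear near the origin) of 6 genes in each library (points) by genotype and treatment, with group means as lines. RSL4 and EXPA7 are nearly absent from untreated rhd6rsl1 and present there with ethylene, and they are low in the quadruple mutant.

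The contrast of ethylene with no treatment in Col-0 asks which genes ethylene moved in wild-type roots. Ethylene raised the root hair factor RSL4 (AT1G27740), from 16.4 ± 2.1 to 43.2 ± 0.79 CPM (log2 fold change 1.40 ± 0.23, adjusted p = 0.00015), and RSL5 (AT5G43175), by 5.28 ± 0.49. It lowered RSL2 (AT4G33880) by 1.63 ± 0.13, RSL3 (AT2G14760) by 1.53 ± 0.27, and the upstream genes RSL1, by 2.03 ± 0.21, and RHD6, by 0.67 ± 0.097. Thus 3 of the 7 root hair bHLH factors rose and 2 fell (3 and 3 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.99). XTH26 (AT4G28850) rose by 3.01 ± 0.27 to 110 ± 6.5 CPM, XTH13 (AT5G57540) by 2.69 ± 0.22 and XTH12 (AT5G57530) by 2.12 ± 0.23, which encode xyloglucan-remodelling enzymes of the root hair wall. EXPA7 (AT1G12560), a root hair expansin, rose by 0.64 ± 0.22 (adjusted p = 0.037) to 151 ± 5.1 CPM. RSL4 lost its call in DESeq2 (adjusted p = 0.22), as did EXPA7 (adjusted p = 0.67). EXPA7 also lost it without any 1 of the 4 Col-0 libraries.

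Of the 29 root hair growth and wall genes 11 rose, 2 fell and 16 were not called in Col-0 (13 up and 2 down adjusted over the list alone). Their median was 0.31 (adjusted p = 0.3). The kinesin MRH2 (AT3G54870) was among the rises, at 0.80 ± 0.11, and RHD4 (AT3G51460) and TRH1 (AT4G23640) went against the list, with falls of 0.27 ± 0.073 and 0.23 ± 0.078. Among 18 root hair specific (RHS) genes 12 rose, 1 fell and 5 were not called (12 up and 2 down adjusted over the list alone), with a median of 0.77 (adjusted p = 0.2). RHS18 (AT5G22410) rose by 1.64 ± 0.23, RHS2 (AT1G12950) by 1.58 ± 0.14, RHS14 (AT4G22080) by 1.43 ± 0.23 and RHS12 (AT3G10710) by 1.27 ± 0.24, while RHS16 (AT4G29180) fell by 0.49 ± 0.12. GL2 (AT1G79840), which keeps epidermal cells hairless, fell by 1.40 ± 0.085, along with MYB23 (AT5G40330), by 1.44 ± 0.19, GL3 (AT5G41315), by 1.08 ± 0.16, and WER (AT5G14750), by 0.69 ± 0.17. In all 5 of 12 epidermal patterning genes fell and 7 were not called (5 adjusted over the list alone), with a median of -0.22 (adjusted p = 0.039, and adjusted p = 0.2 with an estimated correlation).

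Genes of ethylene feedback rose broadly in Col-0. EBF2 (AT5G25350), whose F-box protein removes EIN3, went from 104 ± 3.7 to 357 ± 14 CPM, a rise of 1.79 ± 0.097 (adjusted p = 4e-10). The receptor gene ETR2 (AT3G23150) rose by 2.25 ± 0.12, the receptor regulator RTE1 (AT2G26070) by 3.03 ± 0.14, and the feedback genes ARL (AT2G44080) and ARGOS (AT3G59900) by 4.41 ± 0.18 and 4.93 ± 0.13. Altogether 14 of 16 genes of ethylene signalling and feedback rose and 2 were not called (14 adjusted over the list alone), with a median of 1.48 (adjusted p = 4.9e-11, and 0.035 with an estimated correlation). All 10 ethylene-responsive transcription factors rose (10 adjusted over the list alone), with a median of 2.06 (adjusted p = 2.2e-09, and adjusted p = 0.069 with an estimated correlation). ORA59 (AT1G06160) rose by 3.46 ± 0.26, EBP (AT3G16770) by 2.42 ± 0.17, EDF3 (AT3G25730) by 2.23 ± 0.16 and TEM1 (AT1G25560) by 1.90 ± 0.14. Of 12 ethylene biosynthesis genes 6 rose, 1 fell and 5 were not called (7 and 1 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0021, and adjusted p = 0.16 with an estimated correlation). ACS9 (AT3G49700) rose by 6.87 ± 0.41 and ACO1 (AT2G19590) by 2.71 ± 0.11, whereas ACS5 (AT5G65800) fell by 3.56 ± 0.24.

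Auxin response genes rose as well, 16 of 22 with 4 falls (16 and 4 adjusted over the list alone) and a median of 1.08 (adjusted p = 3.7e-06, and adjusted p = 0.056 with an estimated correlation). IAA1 (AT4G14560) rose by 2.56 ± 0.13, GH3.2 (AT4G37390) by 1.95 ± 0.13, IAA2 (AT3G23030) by 1.64 ± 0.1 and GH3.5 (AT4G27260) by 1.60 ± 0.11, against falls of HAT2 (AT5G47370) by 0.61 ± 0.091, IAA14 (AT4G14550) by 0.74 ± 0.12, LBD18 (AT2G45420) by 0.79 ± 0.21 and GH3.1 (AT2G14960) by 0.66 ± 0.18. Auxin biosynthesis and transport genes were mixed, 5 up and 6 down of 20 (6 and 9 adjusted over the list alone), with a median of -0.17 (adjusted p = 0.76). YUC9 (AT1G04180) rose by 1.26 ± 0.16, TAR2 (AT4G24670) by 0.76 ± 0.15 and ASA1 (AT5G05730) by 0.58 ± 0.091, and the carrier gene AUX1 (AT2G38120) fell by 0.65 ± 0.076. Of 14 cell cycle and meristem genes 12 fell and 2 were not called (13 adjusted over the list alone), with a median of -0.62 (adjusted p = 7.6e-06, and adjusted p = 0.3 with an estimated correlation). The mitotic genes CYCB1;2 (AT5G06150) and AUR1 (AT4G32830) fell by 0.97 ± 0.086 and 0.85 ± 0.14, and CDKB2;1 (AT1G76540) and KN (AT1G08560) by 0.74 ± 0.098 and 0.67 ± 0.097. Among 8 endodermis markers 5 fell and 3 were not called (5 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.002, and adjusted p = 0.45 with an estimated correlation). The Casparian strip gene CASP5 (AT5G15290) fell by 1.76 ± 0.15 and SHR (AT4G37650) by 0.75 ± 0.088.

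The remaining lists had no camera call in Col-0. The iron transporter gene IRT2 (AT4G19680) rose by 0.85 ± 0.17 and BHLH101 (AT5G04150) fell by 1.03 ± 0.23 among 21 iron genes, of which 4 rose and 4 fell (4 and 4 adjusted over the list alone, adjusted p = 0.85). The lipid remodelling genes MGD2 (AT5G20410) and SQD2 (AT5G01220) fell by 1.79 ± 0.22 and 1.31 ± 0.083 among 17 phosphate genes, with 1 up and 3 down (1 and 3 adjusted over the list alone, adjusted p = 0.41). The root cap factors BRN2 (AT4G10350) and SMB (AT1G79580) fell by 1.47 ± 0.21 and 0.96 ± 0.22, 2 of 3 markers (2 adjusted over the list alone, adjusted p = 0.3). TCH3 (AT2G41100) rose by 2.66 ± 0.13 and ZAT10 (AT1G27730) by 1.08 ± 0.19, 2 of 4 rises among 14 touch and stress genes (4 adjusted over the list alone, adjusted p = 0.096). HSP101 (AT1G74310) and HSFA2 (AT2G26150) rose by 0.67 ± 0.12 and 1.25 ± 0.27 among 6 heat shock genes (2 adjusted over the list alone, adjusted p = 0.38). The clock genes LHY (AT1G01060) and CCA1 (AT2G46830) fell by 1.08 ± 0.14 and 0.96 ± 0.16 among 13, with 4 up and 4 down (5 and 4 adjusted over the list alone, adjusted p = 0.96). Of 11 vascular markers 1 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.67). CAB2 (AT1G29920), CAB3 (AT1G29910) and RBCS3B (AT5G38410) were called up in Col-0, at 5.84 ± 1.7, 5.70 ± 1.7 and 4.35 ± 1.5, with an adjusted p = 0.5 for the list, and these genes followed Col-0_ethylene replicate 1. CAB2 stood at 67.4 CPM in that library and 0.299 CPM in replicate 2. How reads shared by near-identical genes, such as CAB2 and CAB3 or XTH12 and XTH13, were assigned is not given in the sources used here.

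Largest changes were read here and below among called genes with a mean of at least 5 CPM. Outside the lists the largest rise in Col-0 was that of the zinc finger gene ZFP2 (AT5G57520), which had no read in the untreated libraries and 14.5 ± 3.8 CPM with ethylene (at least 384-fold against a floor of 3 reads). The carbonic anhydrase gene BCA3 (AT1G23730) rose by 6.81 ± 0.29, the lipase gene AT5G45950 by 6.88 ± 0.62 and the phosphatase gene AT5G02760 by 5.04 ± 0.43. The peroxidase genes AT5G19890 and AT1G49570 rose by 6.20 ± 0.34 and 5.71 ± 0.14, the former from 4.46 ± 1.6 to 327 ± 28 CPM. The pectin lyase-like gene AT1G05650 fell by 6.34 ± 0.26, and the adjacent lipid-transfer-like genes AT5G46890 and AT5G46900 fell by 6.27 ± 0.18 and 5.89 ± 0.18. AT5G04120, a phosphoglycerate mutase-like gene, fell by 5.41 ± 0.32 and the expansin gene EXPA17 (AT4G01630) fell by 5.26 ± 0.16. AT4G37950, AT4G25250 and AT4G22460 fell by 5.17 ± 0.24, 4.77 ± 0.15 and 4.76 ± 0.19, which encode a rhamnogalacturonate lyase, a pectin methylesterase inhibitor-like protein and a lipid-transfer-like protein. In total 6609 of 22304 loci were called, 3061 up and 3548 down, of which 1807 moved at least 2-fold, and without Col-0_untreated replicate 1 the count was 4389. The treated libraries were of set S and the untreated of set Z, so part of these changes cannot be told apart from a set effect.

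**Figure D3:**
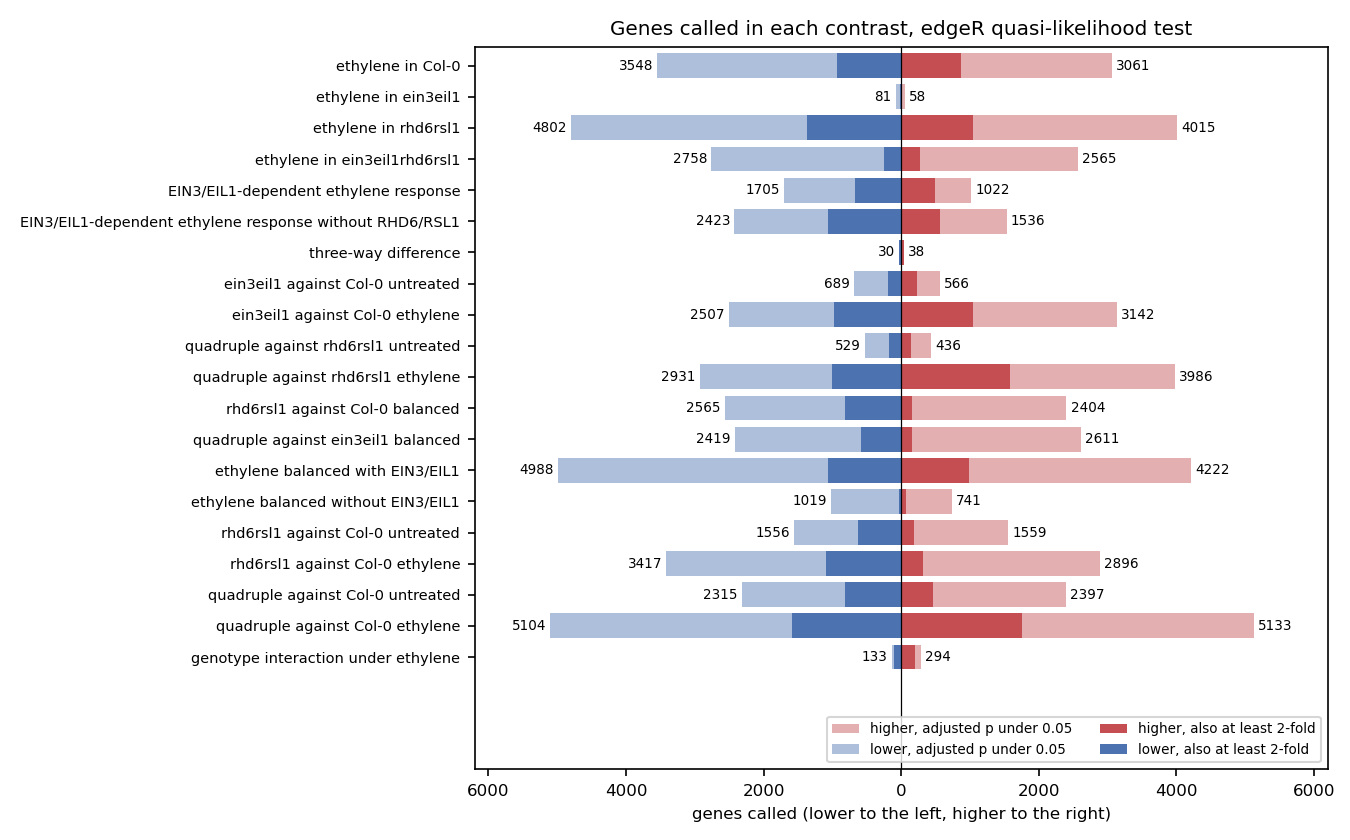
Number of loci called lower (left) and higher (right) in each contrast at an adjusted p below 0.05, with changes of at least 2-fold in darker shade. Of the ethylene contrasts within 1 genotype that in ein3eil1 has the fewest calls.

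The difference of the ethylene responses of Col-0 and ein3eil1 asks which of these changes needed EIN3/EIL1, and an additive set effect cancels in it. EBF2 depended on EIN3/EIL1, at 2.27 ± 0.14 (adjusted p = 9.6e-09). EBF2 stood at 13.2 ± 0.95 CPM in ein3eil1 with ethylene against 357 ± 14 CPM in Col-0. RSL4 depended on EIN3/EIL1 by 1.23 ± 0.32 (adjusted p = 0.018), with 11.7 ± 0.51 CPM untreated and 13.2 ± 1.2 CPM treated in ein3eil1, though DESeq2 did not call it (adjusted p = 0.62). Its call was lost without ein3eil1_ethylene replicate 1 or 2 (adjusted p = 0.051 and 0.087), ein3eil1_untreated replicate 1 or 2 (adjusted p = 0.052 and 0.076) or Col-0_untreated replicate 1 (adjusted p = 0.093). In a fit of the 4 groups compared alone its adjusted p was 0.00013. The falls of RSL2 and RSL3 were dependent, at -1.65 ± 0.18 and -1.72 ± 0.38, as were those of RSL1, at -1.93 ± 0.28, and RHD6, at -0.45 ± 0.14. EXPA7 had a dependence of 0.51 ± 0.31, which was not called (adjusted p = 0.36) except in a fit of the groups compared alone (adjusted p = 0.012) and without the filter on low counts (adjusted p = 0.0029). XTH26 went from 0.574 ± 0.12 to 3.88 ± 0.64 CPM in ein3eil1, and its dependence of 0.28 ± 0.57 was not called (adjusted p = 0.83). XTH13 was at 1.83 ± 0.31, XTH12 at 1.42 ± 0.32 and MRH2 at 0.73 ± 0.16, among 3 positive and 1 negative calls of 29 root hair growth and wall genes (3 and 1 adjusted over the list alone, adjusted p = 1). RHD4 was the negative one. RHS2 and RHS18 were at 1.27 ± 0.2 and 1.19 ± 0.32 and RHS16 was negative, so 2 of 18 RHS genes were positive and 1 negative (3 and 2 adjusted over the list alone, adjusted p = 0.57).

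Ethylene signalling and feedback genes depended on EIN3/EIL1 in 10 of 16 cases with 6 not called (11 adjusted over the list alone), with a median of 1.17 (adjusted p = 1.8e-12, and 0.035 with an estimated correlation). RTE1 was at 2.85 ± 0.2 and the receptor gene ERS2 (AT1G04310) at 2.07 ± 0.18. Among ethylene-responsive transcription factors 9 of 10 were positive (9 adjusted over the list alone), with a median of 1.71 (adjusted p = 5.3e-09, and adjusted p = 0.071 with an estimated correlation). ORA59 was at 3.67 ± 0.44, EBP at 2.73 ± 0.27, EDF3 at 1.94 ± 0.22 and RAV2 (AT1G68840) at 1.25 ± 0.15. Of 12 biosynthesis genes 4 were positive and 1 negative (6 and 1 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.00075, and adjusted p = 0.14 with an estimated correlation). ACO1 and ACO4 (AT1G05010) were at 2.70 ± 0.15 and 1.21 ± 0.18. Auxin response genes were positive in 13 and negative in 2 of 22 cases (13 and 2 adjusted over the list alone), with a median of 0.81 (adjusted p = 2.5e-06, and adjusted p = 0.055 with an estimated correlation). IAA1, GH3.2, GH3.5 and IAA2 were at 1.99 ± 0.19, 1.59 ± 0.19, 1.54 ± 0.16 and 1.41 ± 0.14. Touch and stress genes, led by TCH3 at 3.22 ± 0.18 and ZAT10 at 1.45 ± 0.28, had 4 positive calls of 14 (7 adjusted over the list alone, adjusted p = 0.00035, and adjusted p = 0.14 with an estimated correlation).

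Cell cycle and meristem genes were negative in 4 of 14 cases (9 negative and 1 positive adjusted over the list alone), with a median of -0.46 (adjusted p = 0.00028, and adjusted p = 0.43 with an estimated correlation). CYCB1;2 and KN were the examples, at -0.86 ± 0.12 and -0.66 ± 0.14. CASP5, at -1.99 ± 0.21, was 1 of 3 negative endodermis markers of 8 (4 adjusted over the list alone, adjusted p = 0.0084, and adjusted p = 0.52 with an estimated correlation). GL2 was at -1.26 ± 0.12, MYB23 at -0.98 ± 0.26 and GL3 at -0.69 ± 0.22, the 3 calls among 12 epidermal patterning genes (5 adjusted over the list alone, adjusted p = 0.1). The largest positive values among called genes were those of BCA3, at 8.56 ± 0.99, AT5G19890, at 6.03 ± 1.3, and the feedback gene ARGOS, at 5.57 ± 0.32. Next were ERF11 (AT1G28370) at 4.94 ± 0.61, AT1G49570 at 4.94 ± 0.55, AT5G40590 at 4.65 ± 0.48, AT5G02760 at 4.46 ± 0.89 and the SAUR-like gene AT5G20820 at 4.30 ± 0.39. ZFP2 had no read in ein3eil1 or in untreated Col-0, so its dependence has no finite fold. It was not called in edgeR (adjusted p = 1) but was called by DESeq2 (adjusted p = 0.00011). Without ein3eil1_untreated replicate 2 the calls of AT5G19890 (adjusted p = 0.18) and AT5G02760 (adjusted p = 0.062) were lost. Negative values were led by AT1G05650, which went from 39.4 ± 0.22 to 0.497 ± 0.42 CPM in Col-0 and from 30.5 ± 1.1 to 28 ± 5.6 CPM in ein3eil1. AT5G46890, AT5G46900, AT4G37950, EXPA17, AT1G05660, AT5G04120 and XTH21 (AT2G18800) came next. AT1G05650 and AT1G05660 are near neighbours on the chromosome, and the strand setting of the counts is not given. Among gene families grouped by annotation after the data had been seen, 22 of 47 arabinogalactan protein genes were negative and 1 positive (median -0.47, adjusted p = 1.5e-10, and adjusted p = 0.33 with an estimated correlation). In total 2727 loci were called, 1022 positive and 1705 negative, with 1769 left without ein3eil1_ethylene replicate 1.

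Ethylene against no treatment within ein3eil1 asks what remained of the response without EIN3/EIL1. BT1 (AT5G63160), a BTB/TAZ protein gene, rose by 1.18 ± 0.19 to 31 ± 8.9 CPM, and the organelle loci ATMG00860 and ATCG00905 rose by 1.17 ± 0.13 and 1.14 ± 0.24. AT5G66815, AT5G62210 and AT1G50060 fell by 1.57 ± 0.24, 1.33 ± 0.27 and 1.17 ± 0.18. EBF2 fell by 0.48 ± 0.11, from 18.5 ± 3.1 to 13.2 ± 0.95 CPM (adjusted p = 0.048), opposite to Col-0, and RSL4 was not called, at 11.7 ± 0.51 and 13.2 ± 1.2 CPM. Without ein3eil1_ethylene replicate 1 the calls of BT1, ATCG00905, AT5G66815, AT5G62210 and AT1G50060 were lost, with adjusted p values of 0.25, 0.23, 0.083, 0.42 and 0.15. Leaving out ein3eil1_untreated replicate 2 ended the same 5 calls, ein3eil1_ethylene replicate 2 ended all of these but BT1, and ein3eil1_untreated replicate 1 ended those of BT1 and AT5G62210. Of 22 auxin response genes 6 rose when adjusted over the list alone but not over all loci, with a median of 0.20 (adjusted p = 0.016, and adjusted p = 0.27 with an estimated correlation). The count was 139 loci, 58 up and 81 down, of 3202 with an unadjusted p below 0.05, and DESeq2 called 523. A fit of only the 2 groups compared called 1279 and one without the filter on low counts 958, so the size of this response depended on the processing. Without 1 library it was 16 (ein3eil1_ethylene replicate 1), 21 (ein3eil1_ethylene replicate 2), 69 (ein3eil1_untreated replicate 1) or 20 (ein3eil1_untreated replicate 2). The treated and untreated libraries were again of sets S and Z. Mitochondrial reads made up 0.153 and 0.174% of the treated and 0.097 and 0.082% of the untreated libraries, so the value of ATMG00860 cannot be told apart from this difference between sets.

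The contrast of ein3eil1 with Col-0 under ethylene asks what the loss of EIN3/EIL1 did in treated roots, with both groups in set S. EBF2 was lower by 4.76 ± 0.11, ETR2 by 6.16 ± 0.16 and ARL by 6.73 ± 0.22. RSL4 was lower by 1.71 ± 0.23 (adjusted p = 2.1e-05), RSL5 by 5.05 ± 0.49 and the bHLH gene LRL1 (AT2G24260) by 0.73 ± 0.087, while RSL2 was higher by 1.34 ± 0.13 and RSL1 by 1.93 ± 0.21. EXPA7 was lower by 1.07 ± 0.22 (adjusted p = 0.0014), XTH26 by 4.82 ± 0.3, XTH13 by 2.96 ± 0.22, XTH12 by 2.63 ± 0.23 and MRH2 by 1.27 ± 0.12. DESeq2 did not call RSL4 (adjusted p = 0.13) or EXPA7 (0.47) here. A fit of these 2 groups alone called both (adjusted p = 3.2e-06 and 3.4e-05). Of the 29 root hair growth and wall genes 19 were lower and 10 not called (19 adjusted over the list alone), with a median of -0.84 (adjusted p = 0.00075, and adjusted p = 0.51 with an estimated correlation). Among 18 RHS genes 14 were lower and 4 not called (14 adjusted over the list alone), with a median of -1.19 (adjusted p = 0.0017, and adjusted p = 0.52 with an estimated correlation). RHS2, RHS14, RHS18 and RHS10 (AT1G70460) were lower by 1.99 ± 0.14, 1.94 ± 0.24, 1.92 ± 0.23 and 0.99 ± 0.1. GL2 was higher by 1.21 ± 0.086 and the receptor kinase gene SCM (AT1G11130) by 1.26 ± 0.14, 2 of 6 epidermal patterning genes that were higher.

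Ethylene signalling and feedback genes were lower in 12 of 16 cases (13 adjusted over the list alone), with a median of -2.62 (adjusted p = 2.2e-14, and 0.029 with an estimated correlation). Ethylene-responsive factors were lower in 9 of 10 cases (9 adjusted over the list alone), with a median of -2.15 (adjusted p = 4.6e-09, and adjusted p = 0.071 with an estimated correlation). ORA59 and EBP were lower by 4.38 ± 0.29 and 4.07 ± 0.19. In ethylene biosynthesis 7 of 12 genes were lower and ACS5 was higher, by 3.5 ± 0.25 (9 and 1 adjusted over the list alone, median -0.91, adjusted p = 3.6e-05, and adjusted p = 0.075 with an estimated correlation). Auxin response genes were lower in 14 and higher in 2 of 22 cases (14 and 2 adjusted over the list alone, median -0.99, adjusted p = 1.4e-05, and adjusted p = 0.069 with an estimated correlation). GH3.2 and IAA1 were lower by 2.26 ± 0.14 and 2.15 ± 0.13, and IAA14 and HAT2 were higher by 0.91 ± 0.12 and 0.63 ± 0.091. Cell cycle genes were higher in 12 of 14 cases with PLT2 (AT1G51190) lower by 0.59 ± 0.18 (12 and 1 adjusted over the list alone, median 0.60, adjusted p = 1.8e-05, and adjusted p = 0.32 with an estimated correlation). CYCB1;2 was higher by 0.83 ± 0.087 and KN by 0.72 ± 0.097. Touch and stress genes were lower in 7 of 14 cases (9 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.17 with an estimated correlation). Vascular markers were higher in 7 and lower in 1 of 11 cases (9 and 1 adjusted over the list alone, adjusted p = 0.014, and adjusted p = 0.51 with an estimated correlation).

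Outside the lists, genes of the Col-0 ethylene response differed most between ein3eil1 and Col-0 under ethylene. ZFP2 and AT5G48175 had no read in ein3eil1 with ethylene and were at least 358-fold and at least 285-fold lower. AT5G19890, BCA3 and AT1G49570 were at -10.14 ± 0.46, -9.68 ± 0.38 and -9.33 ± 0.19, and AT5G45950, the CAP-domain gene AT4G33720 and ARGOS at -8.06 ± 0.71, -7.76 ± 0.83 and -7.60 ± 0.16. AT5G46890, AT1G05650, AT5G46900 and AT5G04120 were higher by 5.93 ± 0.18, 5.85 ± 0.27, 5.65 ± 0.18 and 5.17 ± 0.32. CYP710A4 (AT2G28860), a sterol desaturase gene, was higher by 5.10 ± 0.21, XTH21 by 4.59 ± 0.19, EXPA17 by 4.54 ± 0.16 and the marneral synthase gene MRN1 (AT5G42600) by 4.46 ± 0.17. Calls numbered 5649, with 3142 higher and 2507 lower.

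In untreated roots the contrast of ein3eil1 with Col-0, both in set Z, asks what EIN3/EIL1 did without added ethylene. EBF2 was lower by 2.49 ± 0.1, ETR2 by 3.64 ± 0.16, ARL by 3.09 ± 0.27 and EBF1 (AT2G25490) by 1.14 ± 0.081. Ethylene signalling and feedback genes were lower in 9 of 16 cases (10 adjusted over the list alone), with a median of -0.81, or -0.82 with genes at the floor set to their bound (adjusted p = 3.1e-14, and 0.029 with an estimated correlation). Ethylene-responsive factors were lower in 2 of 10 cases, with EBP at -1.34 ± 0.19 (5 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.31 with an estimated correlation). Root hair growth and wall genes were lower in 14 of 29 cases (24 adjusted over the list alone), with a median of -0.66 (adjusted p = 2.9e-08, and adjusted p = 0.23 with an estimated correlation). The peroxidase gene PRX44 (AT4G26010) was lower by 0.96 ± 0.11, LRX2 (AT1G62440) by 0.69 ± 0.12 and XTH12 by 1.21 ± 0.23. RHS genes were lower in 12 of 18 cases (18 adjusted over the list alone), with a median of -0.72 (adjusted p = 6.2e-05, and adjusted p = 0.4 with an estimated correlation). RHS19 (AT5G67400), RHS10, RHS2 and RHS16 were lower by 1.15 ± 0.23, 0.78 ± 0.1, 0.72 ± 0.14 and 0.69 ± 0.12. RSL4, RSL2 and EXPA7 had values of -0.48 ± 0.23, -0.31 ± 0.13 and -0.57 ± 0.22 without a call (adjusted p = 0.3, 0.22 and 0.19).

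Phosphate starvation genes were also lower in untreated ein3eil1, in 4 of 17 cases with 1 higher (7 and 2 adjusted over the list alone, adjusted p = 0.0018, and adjusted p = 0.26 with an estimated correlation). PHT1;9 (AT1G76430) was lower by 1.53 ± 0.29, SPX1 (AT5G20150) by 0.80 ± 0.15 and AT4 (AT5G03545) by 0.74 ± 0.13, while PHO2 (AT2G33770) was higher by 0.77 ± 0.18. Among called genes with a mean of at least 5 CPM the largest changes were those of AT5G19250, a GPI-anchored protein gene, which was lower by 4.85 ± 0.12, XTH26, lower by 4.54 ± 0.39, and LEA7 (AT1G52690), lower by 3.67 ± 0.56. TLL1 (AT1G45201), AT3G58550 and MLP328 (AT2G01520) were higher by 3.44 ± 0.29, 3.1 ± 0.31 and 3.01 ± 0.19. AT5G19250 was at 2.84 ± 0.19 CPM in untreated ein3eil1 but at 65.4 ± 8.9 CPM in the untreated quadruple mutant, so its low level did not follow the loss of EIN3/EIL1 alone. Calls numbered 1255, with 566 higher and 689 lower. The count fell to 575 and 633 without Col-0_untreated replicate 1 or 2, and to 665 and 514 without ein3eil1_untreated replicate 1 or 2, and it was 2134 in a fit of only the groups compared and 1899 without the filter on low counts.

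**Figure D4:**
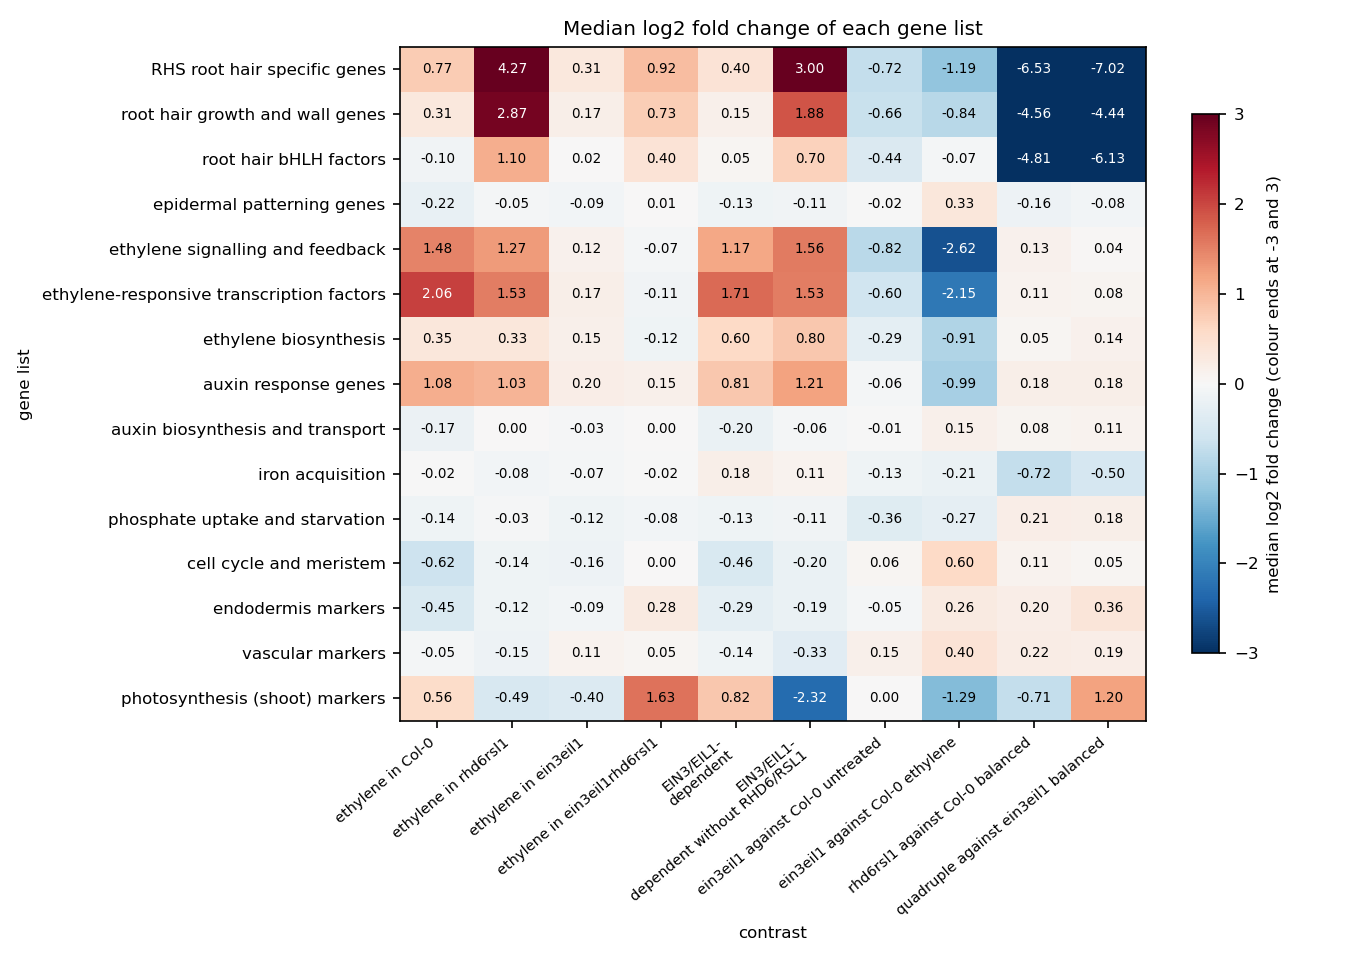
Median log2 fold change of 15 gene lists (vertical) in 10 contrasts (horizontal), with genes at the floor set to their bound. Medians of root hair lists are low in rhd6rsl1, where the bHLH list loses its call with an estimated correlation (adjusted p = 0.18). In the EIN3/EIL1-dependent response medians of ethylene and auxin response lists are positive, but the call is lost in this way for auxin response (adjusted p = 0.055), ethylene-responsive factors (0.071) and biosynthesis (0.14).

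Which genes need RHD6/RSL1 was asked by rhd6rsl1 against Col-0, averaged over both treatments so that an additive set effect cancels. RSL2 was lower by 6.90 ± 0.17, RSL4 by 4.81 ± 0.26 and LRL3 (AT5G58010) by 5.35 ± 0.16, and LRL1 was higher by 0.42 ± 0.061. EXPA7 was lower by 7.09 ± 0.3, going from 96.8 ± 7.6 CPM in untreated Col-0 to 0.0259 ± 0.037 CPM in untreated rhd6rsl1, a ratio of 3840-fold (1060 to 31800) with its 95% counting interval. EXPA18 (AT1G62980) was lower by 6.76 ± 0.15, PRX44 by 3.53 ± 0.085, the kinase gene IRE (AT5G62310) by 4.84 ± 0.12 and MRH2 by 3.67 ± 0.1. Of 29 root hair growth and wall genes 28 were lower and 1 not called (28 adjusted over the list alone), with a median of -4.56 (adjusted p = 4.2e-30, and 0.039 with an estimated correlation). All 18 RHS genes were lower (18 adjusted over the list alone), with a median of -6.50, or -6.53 at the bound (adjusted p = 5.1e-26, and 0.039 with an estimated correlation). RHS6 (AT1G51880), RHS16, RHS2 and RHS10 were lower by 7.77 ± 0.21, 6.18 ± 0.13, 5.54 ± 0.14 and 4.17 ± 0.092. The root hair bHLH factors had 5 lower and 1 higher of 7 (5 and 1 adjusted over the list alone), with a median of -4.84, or -4.81 at the bound (adjusted p = 0.00074, and adjusted p = 0.18 with an estimated correlation).

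Iron acquisition genes were lower in rhd6rsl1 in 15 and higher in 1 of 21 cases (18 and 2 adjusted over the list alone), with a median of -0.72 (adjusted p = 6.1e-07, and adjusted p = 0.41 with an estimated correlation). IRT2 was lower by 2.95 ± 0.14, the iron peptide gene IMA1 (AT1G47400) by 2.49 ± 0.29, IMA2 (AT1G47395) by 2.17 ± 0.26 and BHLH38 (AT3G56970) by 1.79 ± 0.15, while the regulator FIT (AT2G28160) was higher by 0.45 ± 0.076. Auxin response genes were higher in 10 of 22 cases (11 adjusted over the list alone), with a median of 0.18 (adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation). GH3.2 and LBD29 (AT3G58190) were higher by 1.36 ± 0.091 and 1.30 ± 0.16. Endodermis markers, with CASP5 at 0.59 ± 0.1, were higher in 4 of 8 cases (5 adjusted over the list alone, adjusted p = 0.0064, and adjusted p = 0.51 with an estimated correlation). Vascular markers were higher in 4 of 11 cases (5 adjusted over the list alone, adjusted p = 0.043, and adjusted p = 0.58 with an estimated correlation). Epidermal patterning genes were higher in 1 and lower in 4 of 12 cases (1 and 5 adjusted over the list alone, adjusted p = 0.5), with JKD (AT5G03150) higher by 0.48 ± 0.064 and GL3, CPC (AT2G46410) and GL2 lower by 0.62 ± 0.11, 0.29 ± 0.095 and 0.24 ± 0.061. GL2 lost its call without Col-0_ethylene replicate 2 (adjusted p = 0.076) or rhd6rsl1_ethylene replicate 2 (adjusted p = 0.063). In ethylene signalling 3 genes were higher and 1 lower of 16 (4 and 1 adjusted over the list alone, adjusted p = 0.21). EIL2 (AT5G21120) was lower by 4.08 ± 0.45 (untreated, 49.5-fold (13.4 to 415) as a ratio of reads), ARL, ETR2 and ERS1 (AT2G40940) were higher by 0.50 ± 0.12, 0.35 ± 0.082 and 0.23 ± 0.055, and EBF2 was at the threshold, at 0.19 ± 0.067 (adjusted p = 0.056, 0.02 in DESeq2 and called in 8 of 17 settings).

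Many of the largest falls in rhd6rsl1 ended in silence. In untreated rhd6rsl1 no read was found for XTH26, AGD11 (AT3G07490), AT1G52660, AT2G06967, RHS12, ERU (AT5G61350) and AT2G47540. In that order they were at least 362-fold, at least 182-fold, at least 407-fold, at least 233-fold, at least 1630-fold, at least 1040-fold and at least 1710-fold lower than in untreated Col-0. ERU encodes a receptor-like kinase of root hair growth. RHS15 (AT4G25220) was 1480-fold (505 to 7160) lower and the peroxidase gene AT1G05240 was lower by 9.09 ± 0.24. Under ethylene GSTU14 (AT1G27140) and AT1G61080 had no read in rhd6rsl1 and were at least 332-fold and at least 319-fold lower. The largest rises were those of AT4G33720, at 4.25 ± 0.3, GSTF14 (AT1G49860), at 2.53 ± 0.17, and MYB112 (AT1G48000), at 2.48 ± 0.15. The sugar transporter gene SWEET11 (AT3G48740) was higher by 1.91 ± 0.13, the nitrate transporter gene NRT2:1 (AT1G08090) by 1.65 ± 0.24 and the osmotin gene OSM34 (AT4G11650) by 1.65 ± 0.14. In the same families ribosomal protein genes were lower in 129 and higher in 3 of 325 cases (median -0.22, adjusted p = 2e-10, and adjusted p = 0.89 with an estimated correlation). Aquaporin genes were higher in 16 and lower in 2 of 26 cases (median 0.36, adjusted p = 7.5e-05, and adjusted p = 0.7 with an estimated correlation), with TIP2;3 (AT5G47450) at 0.98 ± 0.084 and TIP2;2 (AT4G17340) at 0.83 ± 0.08. AT1G67148 and AT4G16260 were higher by 1.61 ± 0.12 and 1.58 ± 0.11. Calls numbered 4969, with 2404 higher and 2565 lower, but of those with at least a 2-fold change 162 were higher and 812 lower.

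At single treatments the same contrast was confounded with the file set. Untreated, 3115 loci were called, and AT4G35820 and AT3G28865 were higher by 2.79 ± 0.37 and 2.77 ± 0.32 besides AT4G33720, at 4.83 ± 0.48. RHS genes had a median of -8.94 (18 of 18 lower, 18 adjusted over the list alone, adjusted p = 8.1e-32, and 0.037 with an estimated correlation). The count was 1360 without rhd6rsl1_untreated replicate 1, and 1647 and 1701 without Col-0_untreated replicate 1 or 2. With ethylene 6313 loci were called, 2896 higher and 3417 lower. RHS genes were then lower in 18 of 18 cases (18 adjusted over the list alone) with a median of -3.79 (adjusted p = 3.1e-14, and adjusted p = 0.096 with an estimated correlation). CYP710A3 (AT2G28850) was higher by 3.77 ± 0.28, AT4G33720 by 3.68 ± 0.37 and GSTF14 by 2.84 ± 0.23.

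The ethylene response of rhd6rsl1 asks whether ethylene acts on root hair genes in the rhd6rsl1 mutant. RSL4 rose by 7.18 ± 0.47, from 0.0778 ± 0.11 to 11.4 ± 0.18 CPM, LRL3 by 6.68 ± 0.3 and LRL1 by 1.10 ± 0.087, and RSL5 rose at least 25.2-fold. RSL2 stayed at 0.14 ± 0.081 CPM (log2 fold change 0.01 ± 0.53, adjusted p = 0.99), and the RHD6 transcript rose by 0.94 ± 0.1 to 15.2 ± 0.61 CPM, near the 15 ± 1.1 CPM of treated Col-0. EXPA7 reached 27.6 ± 1.8 CPM, 1100-fold (304 to 9070) its untreated level with the 95% counting interval, which was still below the 96.8 ± 7.6 CPM of untreated Col-0. RHS12 rose at least 322-fold and ERU at least 237-fold from no read. EXPA18 and the phosphatidylinositol transfer gene COW1 (AT4G34580) rose by 5.77 ± 0.31 and 3.67 ± 0.22. Root hair growth and wall genes rose in 17 and fell in 6 of 29 cases (17 and 6 adjusted over the list alone), with a median of 2.87 (adjusted p = 0.00046, and adjusted p = 0.5 with an estimated correlation). PCAP2 (AT5G44610) and RHD4 fell by 1.01 ± 0.13 and 0.51 ± 0.074. RHS genes rose in 14 and fell in 1 of 18 cases (15 and 1 adjusted over the list alone), with a median of 5.15, or 4.27 at the bound (adjusted p = 1.4e-08, and adjusted p = 0.2 with an estimated correlation). RHS8 (AT1G63450), RHS10 and RHS3 (AT1G16440) rose by 7.12 ± 0.45, 3.82 ± 0.15 and 3.56 ± 0.2, and RHS17 (AT4G38390) fell by 0.74 ± 0.23. Root hair bHLH factors rose in 5 of 7 cases (5 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.2 with an estimated correlation).

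Outside root hairs the ethylene feedback genes rose in rhd6rsl1 too. EBF2 rose by 1.09 ± 0.096, and 11 of 16 signalling and feedback genes rose with 1 fall (11 and 1 adjusted over the list alone, 0.042 as the adjusted p with an estimated correlation). Auxin response genes rose in 17 and fell in 2 of 22 cases (18 and 2 adjusted over the list alone, adjusted p = 1.7e-07, and 0.039 with an estimated correlation). ZFP2 rose at least 396-fold, and AT5G04120, AT1G05650 and AT5G46900 fell, at -6.47 ± 0.32, -6.39 ± 0.27 and -5.84 ± 0.18. In total 4015 loci rose and 4802 fell. Both Col-0 and rhd6rsl1 raised 1514 loci (551 for independent lists) and lowered 2138 (763.9), and 276 and 170 loci moved in opposite directions. The untreated rhd6rsl1 libraries were of set S and the treated of set Z, the reverse of Col-0.

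Ethylene in the quadruple mutant, against its untreated roots, asks what remained when all 4 genes were mutated. AT3G54580, an extensin-like gene, rose by 3.61 ± 0.73, AT2G10940 by 3.08 ± 1 and PSAH2 (AT1G52230) by 2.91 ± 0.95, and AT3G28865, AT4G35820 and PUX3 (AT4G22150) fell by 2.73 ± 0.32, 2.59 ± 0.37 and 2.12 ± 0.27. EXPA7 rose to 0.827 ± 1.1 CPM (adjusted p = 0.0088), with 55 of its reads in replicate 1 and 2 in replicate 2, and RSL4 was not called, at 0.232 ± 0.33 CPM. Without ein3eil1rhd6rsl1_ethylene replicate 1 the calls of AT3G54580, AT2G10940 and PSAH2 were lost (adjusted p = 0.2, 0.91 and 0.95). AT2G10940 and PSAH2 also lost theirs without ein3eil1rhd6rsl1_untreated replicate 1 (adjusted p = 0.14 and 0.14) or 2 (adjusted p = 0.19 and 0.16). RHS genes rose in 10 of 18 cases (11 adjusted over the list alone), with a median of 1.26, or 0.92 at the bound (adjusted p = 0.015, and adjusted p = 0.63 with an estimated correlation). Growth and wall genes of root hairs rose in 15 and fell in 1 of 29 cases (16 and 1 adjusted over the list alone, adjusted p = 0.0064, and adjusted p = 0.62 with an estimated correlation). Photosynthesis genes rose in 11 of 17 cases (13 adjusted over the list alone, adjusted p = 0.047, and adjusted p = 0.85 with an estimated correlation). Both sets followed ein3eil1rhd6rsl1_ethylene replicate 1. The median over 47 root hair genes was 2.2 CPM there, 0.355 CPM in replicate 2 and 0.282 to 0.284 CPM untreated. Calls numbered 5323, or 2602 in a fit of only the 2 groups compared, with 2745 left without ein3eil1rhd6rsl1_untreated replicate 2 and 3248 and 3268 without ein3eil1rhd6rsl1_ethylene replicate 1 or 2. Treated and untreated libraries were again of different sets.

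The quadruple mutant against rhd6rsl1 asks what EIN3/EIL1 did in the rhd6rsl1 background, within 1 file set at each treatment. Under ethylene RSL4 was at 0.232 ± 0.33 CPM in the quadruple mutant against 11.4 ± 0.18 CPM in rhd6rsl1, and EXPA7 at 0.827 ± 1.1 against 27.6 ± 1.8 CPM. RHS genes were lower in 13 and higher in 1 of 18 cases (13 and 1 adjusted over the list alone, median -3.1, adjusted p = 2e-07, and adjusted p = 0.23 with an estimated correlation). Root hair growth and wall genes were lower in 17 and higher in 5 of 29 cases (17 and 6 adjusted over the list alone, median -1.82, adjusted p = 0.0008, and adjusted p = 0.52 with an estimated correlation). Signalling and feedback genes were lower in 14 of 16 cases (14 adjusted over the list alone, median -2.63, adjusted p = 2.5e-14, and 0.029 with an estimated correlation). Auxin response genes were lower in 14 and higher in 2 of 22 cases (15 and 2 adjusted over the list alone, adjusted p = 2e-06, and adjusted p = 0.055 with an estimated correlation). AT4G33720, AT5G19890 and AT1G49570 were lower, at -11.34 ± 0.7, -9.69 ± 0.42 and -9.47 ± 0.19, and AT5G46890 and AT5G46900 were higher by 6.37 ± 0.18 and 6.18 ± 0.18. LHCB2.2 (AT2G05070), higher by 6.31 ± 1.5, belonged to the photosynthesis genes high in ein3eil1rhd6rsl1_ethylene replicate 1, without which its call was lost (adjusted p = 0.31), as without rhd6rsl1_ethylene replicate 2 (adjusted p = 0.052). In total 3986 loci were higher and 2931 lower.

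Untreated, the quadruple mutant had 436 higher and 529 lower loci than rhd6rsl1. AT4G33720, AT5G19890 and AT1G49570 were lower, at -6.70 ± 0.59, -5.62 ± 0.47 and -4.96 ± 0.21, and MLP328, CYP710A4 and AT1G14120 were higher by 3.13 ± 0.19, 2.94 ± 0.16 and 2.72 ± 0.28. Signalling and feedback genes were lower in 10 of 16 cases (11 adjusted over the list alone, adjusted p = 2.6e-15, and 0.029 with an estimated correlation). Ethylene-responsive factors were lower in 5 of 10 cases (6 lower and 1 higher adjusted over the list alone, adjusted p = 8.4e-06, and adjusted p = 0.15 with an estimated correlation). The count of 965 became 463 and 482 without rhd6rsl1_untreated replicate 1 or 2, and 3357 and 485 without ein3eil1rhd6rsl1_untreated replicate 1 or 2. It was 604 in a fit of only the groups compared and 2084 without the filter on low counts.

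The EIN3/EIL1-dependent response in the rhd6rsl1 mutant, rhd6rsl1 minus the quadruple mutant, asks whether that dependence holds in the rhd6rsl1 background. GH9C1 (AT1G48930), a cellulase-like root hair gene, was at 6.97 ± 1.3, DIR5 (AT1G64160) at 6.12 ± 0.85 and AT5G40590 at 5.29 ± 0.55, and AT1G05650, AT5G46890 and AT5G46900 were at -6.27 ± 0.33, -6.23 ± 0.22 and -6.22 ± 0.23. RHS genes were positive in 7 and negative in 1 of 18 cases (7 and 1 adjusted over the list alone), with a median of 2.5, or 3.0 at the bound (adjusted p = 1.7e-07, and adjusted p = 0.23 with an estimated correlation). Root hair growth and wall genes were positive in 6 and negative in 5 of 29 cases (7 and 6 adjusted over the list alone, median 1.69, or 1.88 at the bound, adjusted p = 0.014, and adjusted p = 0.65 with an estimated correlation). Signalling and feedback genes were positive in 10 of 16 cases (11 adjusted over the list alone, median 1.17, or 1.56 at the bound, adjusted p = 1.5e-11, and 0.035 with an estimated correlation). Auxin response genes were positive in 14 and negative in 1 of 22 cases (15 and 1 adjusted over the list alone, adjusted p = 1.2e-07, and 0.039 with an estimated correlation). Photosynthesis genes were negative in 7 of 17 cases (11 adjusted over the list alone, adjusted p = 0.038, and adjusted p = 0.85 with an estimated correlation), which followed ein3eil1rhd6rsl1_ethylene replicate 1. Calls numbered 3959, with 1536 positive and 2423 negative. Of these 679 were positive and 1405 negative in the Col-0 background too (70.4 and 185.2 for independent lists), and 3 and 3 had opposite signs.

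Whether that dependence differed with RHD6/RSL1 was asked by the three-way difference. RHS genes were negative in 4 of 18 cases (6 adjusted over the list alone), with a median of -2.10, or -2.36 at the bound (adjusted p = 1.1e-13, and adjusted p = 0.1 with an estimated correlation). RHS10, RHS16 and RHS3 were at -2.83 ± 0.29, -2.71 ± 0.54 and -2.12 ± 0.41, so on the log2 scale their EIN3/EIL1 dependence was more positive in the rhd6rsl1 background. For RHS16 it changed sign, from -0.79 ± 0.16 in the Col-0 background to 1.92 ± 0.52 (adjusted p = 0.016). RHS8, the fourth, was at -8.75 ± 1.4 (adjusted p = 0.0054), with 0.0518 ± 0.073 CPM in untreated rhd6rsl1, and lost its call without ein3eil1rhd6rsl1_untreated replicate 1 (adjusted p = 0.32). Genes of root hair growth and walls were negative in 6 of 29 cases (6 negative and 1 positive adjusted over the list alone, median -0.65, or -0.69 at the bound, adjusted p = 5.3e-05, and adjusted p = 0.43 with an estimated correlation). EXPA18, COW1, GEF3 (AT4G00460) and MRH2 were at -4.52 ± 0.74, -2.74 ± 0.48, -2.48 ± 0.39 and -1.61 ± 0.3. ERU was the largest negative call (adjusted p = 0.033), without a finite fold as it had no read in untreated rhd6rsl1. It lost the call without any 1 library of untreated rhd6rsl1, Col-0 or ein3eil1, without ein3eil1_ethylene replicate 1 (adjusted p = 0.057) and without ein3eil1rhd6rsl1_untreated replicate 1 (adjusted p = 1). LRL3, at -6.74 ± 0.88, was the call among 7 bHLH factors (1 adjusted over the list alone, adjusted p = 4.6e-05, and adjusted p = 0.11 with an estimated correlation). LRL3 lost its call without ein3eil1rhd6rsl1_untreated replicate 2 (adjusted p = 0.16). RHD6 itself was at -1.07 ± 0.2 (adjusted p = 0.029). RSL4 was at -3.72 ± 1.8 and EXPA7 at -5.36 ± 2.6 without calls (adjusted p = 0.88 and 0.89), at 0.0778 ± 0.11 and 0.0259 ± 0.037 CPM in untreated rhd6rsl1. AT3G18450, AT3G50130 and RAB7A (AT2G21880) were at 5.38 ± 0.6, 4.43 ± 0.55 and 3.81 ± 0.26. In total 38 loci were positive and 30 negative, 68 in all, with 134 called without Col-0_ethylene replicate 2, 44 without ein3eil1_ethylene replicate 1, 37 without Col-0_untreated replicate 1 and 39 without ein3eil1_untreated replicate 2. DESeq2 called 130, and 424 were called without the filter on low counts. Planted 2-fold changes were recovered in 27.9% of cases here and 4-fold in 77.4%, which may not hold for silent genes.

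The effect of ein3eil1 under ethylene was also set against the presence of RHD6/RSL1, as the difference between the quadruple mutant against rhd6rsl1 and ein3eil1 against Col-0. RHS8 was at -6.98 ± 0.52 and AT5G19250 at 5.2 ± 0.16, the latter because it was low in ein3eil1 alone. RBCS3B and LHCB2.1 (AT2G05100), at 11.73 ± 2.5 and 6.03 ± 1.3, followed the 2 libraries with high photosynthesis transcripts. Without both libraries these 2 genes were at 0.59 and 1.06 (adjusted p = 0.99 and 0.8), and their calls were lost without Col-0_ethylene replicate 1, ein3eil1rhd6rsl1_ethylene replicate 1, or any 1 library of ein3eil1_ethylene or rhd6rsl1_ethylene. RHS genes were negative in 8 of 18 cases (11 negative and 1 positive adjusted over the list alone, adjusted p = 1.7e-08, and adjusted p = 0.2 with an estimated correlation). Photosynthesis genes were positive in 11 of 17 cases (17 adjusted over the list alone, adjusted p = 9e-09, and adjusted p = 0.46 with an estimated correlation). Of 427 calls, 294 were positive and 133 negative, with 253 left without Col-0_ethylene replicate 1, 258 without ein3eil1_ethylene replicate 2 and 265 without rhd6rsl1_ethylene replicate 1, and 927 called without the filter on low counts.

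The quadruple mutant against ein3eil1, averaged over both treatments, asks what RHD6/RSL1 did in roots without EIN3/EIL1. All 18 RHS genes were lower (18 adjusted over the list alone), with a median of -7.33, or -7.02 at the bound (adjusted p = 9.6e-29, and 0.039 with an estimated correlation). Of 29 root hair growth and wall genes 26 were lower (27 adjusted over the list alone), with a median of -5.13, or -4.44 at the bound (adjusted p = 1.2e-28, and 0.039 with an estimated correlation). AT2G34910 and MRH6 (AT2G03720) had no read in the untreated quadruple mutant, against 28.3 ± 2.3 and 27.7 ± 1.2 CPM in untreated ein3eil1. Iron genes were lower in 11 of 21 cases (13 adjusted over the list alone, adjusted p = 0.00036, and adjusted p = 0.56 with an estimated correlation). Endodermis markers were higher in 8 of 8 cases (8 adjusted over the list alone, adjusted p = 1.6e-05, and adjusted p = 0.25 with an estimated correlation). AT5G19250 was higher by 5.12 ± 0.087, GH9B17 (AT4G39000) by 2.15 ± 0.14 and LHB1B1 (AT2G34430), a photosynthesis gene, by 3.52 ± 1.1. LHB1B1 was at 0.39 without ein3eil1rhd6rsl1_ethylene replicate 1 (adjusted p = 0.78), and its call was also lost without any 1 other library except ein3eil1rhd6rsl1_ethylene replicate 2. In total 2611 loci were higher and 2419 lower, 5030 in all, with 3232 called without ein3eil1_ethylene replicate 2 and 3203 without ein3eil1_untreated replicate 1. With rhd6rsl1 against Col-0, which shared no library, 1495 higher and 1586 lower loci were common (281.4 and 278.2 for independent lists), and 11 and 19 had opposite signs.

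The quadruple mutant was also set against Col-0, to ask what the loss of all 4 genes did, in contrasts confounded with the file set. Untreated, MLP328, CYP710A4 and AIR1 (AT4G12550) were higher by 4.11 ± 0.2, 3.59 ± 0.17 and 3.57 ± 0.13, and RHS15 was at least 1580-fold lower. Of 4712 calls 2397 were higher, with 3027 calls without ein3eil1rhd6rsl1_untreated replicate 2, 2699 without Col-0_untreated replicate 1 and 2833 without Col-0_untreated replicate 2, and 2986 in a fit of only the groups compared. Under ethylene AT5G46890, AT5G46900 and CYP710A4 were higher by 6.74 ± 0.18, 6.4 ± 0.19 and 6.17 ± 0.21, and AT5G43230, LOG2 (AT2G35990) and RHS4 (AT1G30850) were at least 520-fold, at least 316-fold and at least 249-fold lower. Of 10237 loci called under ethylene 5133 were higher and 5104 lower.

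Ethylene effects were last averaged over genotypes, so an additive set effect cancels. With EIN3/EIL1 (Col-0 and rhd6rsl1) ACS9 and AT5G45950 rose by 7.76 ± 0.32 and 7.05 ± 0.4 (for ACS9, 456-fold (126 to 3770) in rhd6rsl1), AT1G05650, AT5G46890 and AT5G04120 fell, at -6.36 ± 0.19, -6.02 ± 0.13 and -5.94 ± 0.23, and 9210 loci were called. Signalling and feedback genes rose in 14 and fell in 1 of 16 cases (14 and 1 adjusted over the list alone, adjusted p = 1.4e-09, and 0.039 with an estimated correlation). Without EIN3/EIL1 (ein3eil1 and the quadruple mutant) FLA6 (AT2G20520), MRH6 and AT5G06630 rose by 4.13 ± 0.73, 3.42 ± 0.75 and 3.16 ± 0.69 (in the quadruple mutant at least 13.2-fold for FLA6 and at least 7.87-fold for MRH6), and AT2G15292, AT2G20724 and AT1G10530 fell by 1.31 ± 0.11, 1.30 ± 0.14 and 1.25 ± 0.16. Without ein3eil1rhd6rsl1_ethylene replicate 1 the calls of FLA6, MRH6 and AT5G06630 were lost. MRH6 and AT5G06630 also lost theirs without ein3eil1_untreated replicate 1, ein3eil1_ethylene replicate 1 or ein3eil1rhd6rsl1_untreated replicate 2. Root hair growth and wall genes rose in 12 of 29 cases there (17 adjusted over the list alone, adjusted p = 7.4e-05, and 0.43 with an estimated correlation). The median of 47 root hair genes rose in ein3eil1 (37.2 and 35.9 to 54 and 45.9 CPM, set Z to S) and in ein3eil1rhd6rsl1_ethylene replicate 1. The count of 1760 became 209 and 232 without ein3eil1_untreated or ein3eil1_ethylene replicate 1, and 1006 without ein3eil1_ethylene replicate 2. It became 4145 and 473 without ein3eil1rhd6rsl1_untreated replicate 1 or 2, and 631 without ein3eil1rhd6rsl1_ethylene replicate 2. A fit of only the groups compared gave 1023, and no count filter 3056.

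The 2 double mutants were compared under ethylene by genes called in both contrasts with Col-0, which share its 2 libraries. Here 714 loci were higher in both and 568 lower (408 and 384.1 for independent lists). Opposite signs were found for 489 and 460 loci (481.4 and 325.5). The correlation was 0.202 against 0.49 in simulations with shared controls and no effect, and the covariance was 0.17 against a simulated 0.0381. XTH26, at 110 ± 6.5 CPM in Col-0, was lower in both, at 3.88 ± 0.64 CPM in ein3eil1 and 0.529 ± 0.35 CPM in rhd6rsl1. The EIN3/EIL1-dependent response and rhd6rsl1 against Col-0 balanced differ in sign where both factor pairs act alike. Such were 96 loci raised and 389 lowered by both (117.5 and 183.8). Signs matched at 287 positive and 279 negative loci (110.2 and 196.1), and the covariance was -0.0367 against a simulated -0.000136.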

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

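Of the tests below, the correlation of ethylene responses and the 4 splits of libraries were written before the result was seen, and the others after it. The ethylene response differed between genotypes for 2727 loci (Col-0 and ein3eil1), 3959 loci (rhd6rsl1 and the quadruple mutant), 4015 loci (Col-0 and rhd6rsl1) and 3791 loci (ein3eil1 and the quadruple mutant). The difference of differences was called for 68 loci, and the ein3eil1 effect under ethylene differed with RHD6/RSL1 for 427 loci. The counts of 4015 and 3791 equal contrasts of file set S with Z and cannot be told apart from a set effect.

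The first pattern was the 5323 loci called for ethylene in the quadruple mutant against 139 in ein3eil1, a gap that narrowed to 2602 against 1279 in fits of only the groups compared and 5865 against 958 without the filter on low counts. If the file set drove these changes, responses in the 2 mutants, whose sets run in opposite directions, should correlate negatively, below -0.1, and the correlation was -0.093 with an SD of 0.054 over libraries left out (Spearman -0.124). The contrasts of set S with Z with and without EIN3/EIL1, which share no library, correlated at 0.34 (Spearman 0.564). The mitochondrial share of reads was 0.148 to 0.204% in S and 0.082 to 0.12% in Z without overlap, so this share follows the set. An additive set effect alone would change both mutants equally, which 5323 against 139 calls argue against. A partial one cannot be told apart from a response that differs with RHD6/RSL1, the same contrast here. Foreign tissue in ein3eil1rhd6rsl1_ethylene replicate 1 may not be the main cause, since 3248 loci were still called without it, nor was length or GC content, with a largest correlation of 0.22.

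The second pattern was the root hair transcripts in ein3eil1rhd6rsl1_ethylene replicate 1, at a median of 2.2 CPM against 0.355 CPM in replicate 2. An admixture of RNA from ethylene-treated Col-0 roots cannot be told apart from other sources. Loci silent in the other quadruple libraries, high in treated Col-0 and also high in treated rhd6rsl1 stood at a median of 0.685% of the Col-0 level against 0.237% in replicate 2, but only 6 loci met these terms, which favour low values in replicate 2. Shoot tissue stays open too, since 12.2% of the root hair loci were at least 1.2 times higher in Col-0_ethylene replicate 1 than in its replicate, but their median in the quadruple library was 0.935% of the Col-0 level, too low for such tissue to give that rise.

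The third pattern was the return of root hair transcripts in rhd6rsl1 under ethylene, where RHD6 and RSL1 stood at 15.2 ± 0.61 and 1.49 ± 0.36 CPM against 15 ± 1.1 and 1.42 ± 0.46 CPM in treated Col-0. Col-0 libraries under a wrong label are unlikely, since loci silent in untreated rhd6rsl1 had a median of at most 7.92% of the Col-0 level and RSL2 was at 0.14 ± 0.081 against 9.63 ± 0.5 CPM. Whether the RHD6 and RSL1 transcripts in rhd6rsl1 keep some function was not tested and stays open. Admixed Col-0 RNA would leave all such loci at 1 share of the Col-0 level, but the 90th percentile of the shares was 29 times the 10th, so admixture alone is unlikely. Of 84 such loci 66, or 78.6%, were lower and 2 higher in the treated quadruple mutant than in treated rhd6rsl1, at a median of 14.9 and 2.25% of that level in replicates 1 and 2, which is consistent with a response that depends on EIN3/EIL1.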

How the results depend on the processing

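The alternatives were fixed before the result was seen, except those using the first model of each locus, leaving out organelle loci and leaving out both libraries high in photosynthesis transcripts, which were added after. Of counts and design results 250 stayed within 1.5-fold, 74 moved further and 1 reversed, and of single genes 2995 stayed, 98 were weaker and 17 stronger. Asking for at least a 2-fold change left 1807 loci for ethylene in Col-0, 23 in ein3eil1, 2414 in rhd6rsl1 and 523 in the quadruple mutant. It left 1172 for the EIN3/EIL1-dependent response and 1637 in the rhd6rsl1 background. For ein3eil1 against Col-0 it left 418 untreated and 2023 with ethylene, and for the quadruple mutant against rhd6rsl1 318 and 2579. It left 974 for rhd6rsl1 against Col-0 balanced, 736 for the quadruple mutant against ein3eil1 balanced, and 2041 and 99 for ethylene balanced with and without EIN3/EIL1. At single treatments it left 817 and 1409 for rhd6rsl1 against Col-0, 1282 and 3335 for the quadruple mutant against Col-0, and an overlap of 288 where the main value was 1282. Without the filter on low counts 958 were called for ethylene in ein3eil1, 424 for the three-way difference, 1899 for ein3eil1 against Col-0 untreated and 2084 for the quadruple mutant against rhd6rsl1 untreated. Ethylene balanced without EIN3/EIL1 then gave 3056 and the genotype interaction 927. DESeq2 gave 523 for ethylene in ein3eil1 and 130 for the three-way difference. Fits of only the groups compared gave 1279 for ethylene in ein3eil1, 2602 in the quadruple mutant, 2134 for ein3eil1 against Col-0 untreated, 604 for the quadruple mutant against rhd6rsl1 untreated, 1023 for ethylene balanced without EIN3/EIL1 and 2986 for the quadruple mutant against Col-0 untreated. Without both libraries high in photosynthesis transcripts 3525 were called for ethylene in the quadruple mutant and 272 for the genotype interaction. Gene lists called fell from 133 to 21 with an estimated correlation.

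Leaving out 1 library at a time gave 4389 to 5144 for ethylene in Col-0, 16 to 69 in ein3eil1, 6479 to 6886 in rhd6rsl1 and 2745 to 6075 in the quadruple mutant. The EIN3/EIL1-dependent response ranged from 1769 to 2465, that in the rhd6rsl1 background from 2818 to 5490 and the three-way difference from 37 to 134. For ein3eil1 against Col-0 the range was 514 to 665 untreated and 4022 to 4489 with ethylene. For the quadruple mutant against rhd6rsl1 it was 463 to 3357 untreated and 5362 to 5491 with ethylene. The balanced contrasts gave 3512 to 4807 for rhd6rsl1 against Col-0, 3203 to 5261 for the quadruple mutant against ein3eil1, and 7721 to 8607 and 209 to 4145 for ethylene with and without EIN3/EIL1. At single treatments rhd6rsl1 against Col-0 gave 1360 to 2298 and 4369 to 4839, and the quadruple mutant against Col-0 2699 to 5882 and 7852 to 9170. The genotype interaction ranged from 253 to 584. Large gains came from leaving out ein3eil1rhd6rsl1_untreated replicate 1. The correlation of ethylene responses without EIN3/EIL1 ranged from -0.126 to 0.043, and its sign reversed without ein3eil1_untreated replicate 2. Over 17708 loci without an EIN3/EIL1-dependent call it was -0.105.

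Replicate number as a block moved no count by more than 1.5-fold, and replicate numbers did not pair libraries, with residual correlations of -0.08 to 0.21 over 28 pairs of groups and 2 above 0.1. Scaling by other size factors moved the median change of all loci by at most 0.03. Single genes were less stable where some groups had almost no reads. RSL4 kept its ethylene call in Col-0 in most settings but not in DESeq2 (adjusted p = 0.22). EXPA7 lost its call there in 5 settings, and ERU lost its three-way call in 8 of 24 settings.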

Other observations

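The splits described here were written before the result was seen, and no further test was chosen after it. The 8 libraries of 2 genotypes were divided into 4 and 4 in all 35 ways, in a fit of 2 groups that leaves the other factor in the residual, so its counts lie below the 4969, 9210, 5030 and 1760 of the fit of group means. For ethylene with EIN3/EIL1 the true division called 4492 loci and the highest other 640 (1 of 35 called as many). For the quadruple mutant against ein3eil1 it called 1634 and the highest other 13 (1 of 35). For rhd6rsl1 against Col-0 the true division called 640 and for ethylene without EIN3/EIL1 13, where 2 of 35 called as many. In each case the other division was the real one by the other factor, with 4492 and 1634 loci, a structure that this fit does not model. Divisions that mixed groups called at most 0 and only 3 kept groups whole, so these counts cannot decide on chance.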
